A study of Rattus norvegicus with 6 samples.

How the data were processed

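MicroRNAs (miRNAs) were measured in plasma RNA of 6 male Wistar rats on a 1-colour Agilent rat miRNA array, 1 array per animal. Per the labels, 3 animals received saline vehicle and 3 received thioacetamide at 100 mg/kg, both into the peritoneum, and plasma was taken 24 h later. Each array was placed in its group by the treatment named in its sample title. Per the labels' protocols, an equal volume of each plasma was extracted with Trizol LS, labelling spike-in RNA was added, and the RNA was joined to a Cy3-carrying nucleotide by a ligase and hybridised. The labels give each array its own body weights, so the arrays were treated as separate animals. The p-values measure the spread between these animals.

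The intensity values deposited by the authors are background-subtracted spot signals on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Some are below 0. They are neither log transformed nor scaled between arrays. The deposited matrix of intensity values equals the processed signal of the scanner files to within 0.005 on every spot, so its scale, centring and direction are known; its median values are 0.99, 0.20 and -2.95 for vehicle 1 to 3 and 0.73, 0.60 and 2.76 for thioacetamide 1 to 3. The scanner files list 13540 miRNA spots and 715 control spots per array. The miRNA spots belong to 1644 probes for 677 miRNAs, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. Probe positions in the rat build rn4 come from the scanner files. Names of miRNAs are those of the array design. A RefSeq gene table of the assembly GRCr8, used for names alone, held a precursor gene symbol for 639 of the 677 miRNAs and for 54 of the 59 tested. No spot was saturated, and 2126 miRNA spots over the 6 arrays carried an outlier mark and were left out, as were the control spots.

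A probe was called detected on an array when over 50% of its unmarked spots were well above background in Feature Extraction's own call, which uses a multiple of 13 per the file headers, and a miRNA when any of its probes was. Unmarked spots of a probe were averaged and the means of a miRNA's probes were summed. Each array was scaled by its 75th percentile over the 12 probes detected on all 6 arrays, which belong to 8 miRNAs. Among these 8 are miR-451, miR-16, miR-25 and miR-92a of the erythrocyte list. A change shared by these would be partly scaled away. The scale factors were 0.936, 0.776 and 0.626 for vehicle 1 to 3 and 2.27, 0.775 and 1.25 for thioacetamide 1 to 3. Scaled sums were then raised to a floor of 46.1, the 5th percentile of the scaled sums of detected miRNAs, and log2 was taken. Changes of miRNAs near the floor depend on it. Tested were the 59 miRNAs detected on at least 3 of the 6 arrays, whatever their group. The fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with 4 residual and 2.41 prior degrees of freedom) with treatment as the only term, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Where no array of a group held a miRNA well above background, its fold is a bound. The bound sets the bright group's mean against the mean, over the dim arrays, of the higher of the lowest signal well above background and the miRNA's own signal. That lowest signal is of a single probe, while a miRNA's signal sums its probes. The bound is taken before the floor and can exceed the fitted fold. It carries no sampling error, so it is not a lower confidence limit. The number of spots above background, which ranged from 212 on vehicle 3 to 1344 on thioacetamide 3, and the number of arrays limit the precision.

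Values with 1 number per array, such as body weight change, were compared with exact two-sided permutation tests of the difference in means, whose smallest possible p with 3 against 3 is 0.1. There were 14 lists of miRNAs: liver, erythrocyte, leukocyte, platelet and endothelial, muscle and heart, brain, pancreas, epithelium with kidney and gut, the let-7 family, the miR-17 cluster with its paralogous clusters, the p53-regulated miR-34 family, stellate cell and fibrosis, the imprinted Dlk1-Dio3 cluster, and plasma reference miRNAs. The 7 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, two-sided) and adjusted over the lists. Camera sets a list's changes against those of the other tested miRNAs, so a list called lower need not have fallen. The miRNAs described by name are those past the threshold whose groups did not overlap (at most 15 higher and 10 lower), every tested member of the liver, erythrocyte and leukocyte lists, up to 4 members of each other list, miRNAs detected on all arrays of one group and none of the other, and the 5 brightest of each group. The comparison, its tests, the lists, this naming rule and most alternatives were chosen before the data were examined.

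The scripts were tested on simulated data for the comparison of thioacetamide with vehicle, with 59 miRNAs of which 20 were changed, in 100 simulations. Without noise the log2 changes came back with an error of 0. With independent noise of the size seen on the arrays, 21.4% of log2 changes of 1 were recovered and 57.2% of those of 2. Of those of 3, 76.2% were recovered and of those of 4, 88.2%, and on average 4.50% of calls were wrong. Of unchanged lists camera called 4%, and of lists shifted by 3 it called 100%. The simulated noise held no correlation between miRNAs and no slide sides. In the data the estimated correlation of the tested lists ran from 0.15 (leukocyte) to 0.77 (let-7), so error rates can be higher there.

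All 6 arrays share 1 slide and 1 scan. Slide columns 1 and 2 held vehicle 2, vehicle 3 and thioacetamide 1, and columns 3 and 4 held vehicle 1, thioacetamide 2 and thioacetamide 3. In columns 1 and 2 the miRNA spots were more widely spread and the negative control spots brighter (mean 138 to 336 against 64.3 to 68.1). The median local background was alike (35 to 37 against 34 to 35). The wider spread is called a noisier background below, and slide side was treated as a batch that holds both groups. Results were recomputed with slide side as a block and within each side, which was chosen after seeing the data. In these fits with 3 arrays, the scaling and floor of all 6 were kept, and the lone array of a group is assumed to vary like the others. Other alternatives were the percentile over all probes, no scaling, quantile normalization, scaling to spike-in probes, the median of miRNAs detected on all arrays, normexp background correction with an offset of 50, other summaries of probes and of detection, the deposited matrix, other filters and floors, array weights, a trended robust eBayes, slide row and replicate number as blocks, and leaving out each animal in turn. With an animal left out, the filter of 3 arrays was applied anew, so 29 to 54 miRNAs were tested and some lists held fewer members. For lists, camera with an estimated correlation and fry were also run. In the list tests camera took the array weights and the variance trend, and has no robust option. The control probes entered no test of miRNAs.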

Results

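Thioacetamide is a liver toxicant that hepatocytes convert into reactive metabolites, and the series asked which plasma miRNAs mark the damage it does. Plasma miRNAs of 3 thioacetamide-treated and 3 vehicle-treated rats were measured 24 h after dosing, with 1 array per animal. Of 677 rat miRNAs on the array, 578 were well above background on none of the 6 arrays, 40 on 1 or 2 arrays and 8 on all 6. The 59 miRNAs detected on at least 3 arrays were compared. The spread of the miRNA spots, most of which lie at background (median absolute deviation, normal-scaled), was 33.3, 35.5 and 96.6 for the arrays in slide columns 1 and 2 (vehicle 2, vehicle 3, thioacetamide 1) against 4.92, 7.83 and 12.8 in columns 3 and 4 (vehicle 1, thioacetamide 2, thioacetamide 3). Both sides of the slide held both groups. Within each side the spread was wider on the thioacetamide arrays, which a block for the side does not remove.

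On the scaled arrays several miRNAs known from liver were higher after thioacetamide, and miR-451, a red blood cell miRNA, was lower. miR-122, the most abundant miRNA of hepatocytes, rose 274-fold (log2 change 8.10 ± 0.61, SE, n = 3 per group, limma adjusted p = 0.000406), from a log2 signal of 5.94 ± 0.39 to 14.04 ± 1.09 (SD). miR-22, which is abundant in liver and several other tissues, rose 55.6-fold (log2 change 5.80 ± 0.54, adjusted p = 0.000725). miR-192, enriched in liver, gut and kidney, rose 18.8-fold (4.23 ± 0.46, adjusted p = 0.00107), and miR-21, a widely expressed miRNA induced in injured and fibrotic tissue, rose 9.32-fold (3.22 ± 0.36, adjusted p = 0.00107). These 4 miRNAs were well above background on all 3 thioacetamide arrays and on 1 of 3 vehicle arrays. One vehicle array held miR-122 at the floor, and its log2 change was 6.51 with a floor 4 times as high and 8.76 with a floor 0.25 times as high. The lowest log2 changes over all alternatives, each with normexp, were 6.04 for miR-122, 4.41 for miR-22, 3.04 for miR-192 and 1.90 for miR-21. Without vehicle 3 the change of miR-122 was 7.12.

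In all, 9 miRNAs rose, 1 fell and 49 did not pass the threshold. At an unadjusted p under 0.05, 16 were higher and 5 lower. The other risers were miR-30a (6.71-fold, log2 change 2.75 ± 0.38, adjusted p = 0.00289), miR-29a, known to repress collagen messenger RNAs (4.32-fold, 2.11 ± 0.35, adjusted p = 0.00760), miR-30d (5.82-fold, 2.54 ± 0.50, adjusted p = 0.0134) and miR-27b (3.58-fold, 1.84 ± 0.45, adjusted p = 0.0353). miR-122*, from the other arm of the miR-122 precursor, was detected on 0 vehicle and 3 thioacetamide arrays and rose at least 5.71-fold (adjusted p = 0.0130). miR-30a and miR-29a were detected on 1 vehicle and 3 thioacetamide arrays, and miR-30d and miR-27b on 1 and 2. For all 10 miRNAs past the threshold the 3 arrays of one group lay on one side of the other 3, and every probe of each moved the same way. Of the 59 tested, 22 (37.3%) separated the groups in this way. Chance gives 10% for a single miRNA, but the 59 share the same 6 arrays and are not independent. The slide sides were likewise separated, with 9 miRNAs brighter and 6 dimmer on all arrays of columns 1 and 2.

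**Figure D1:**
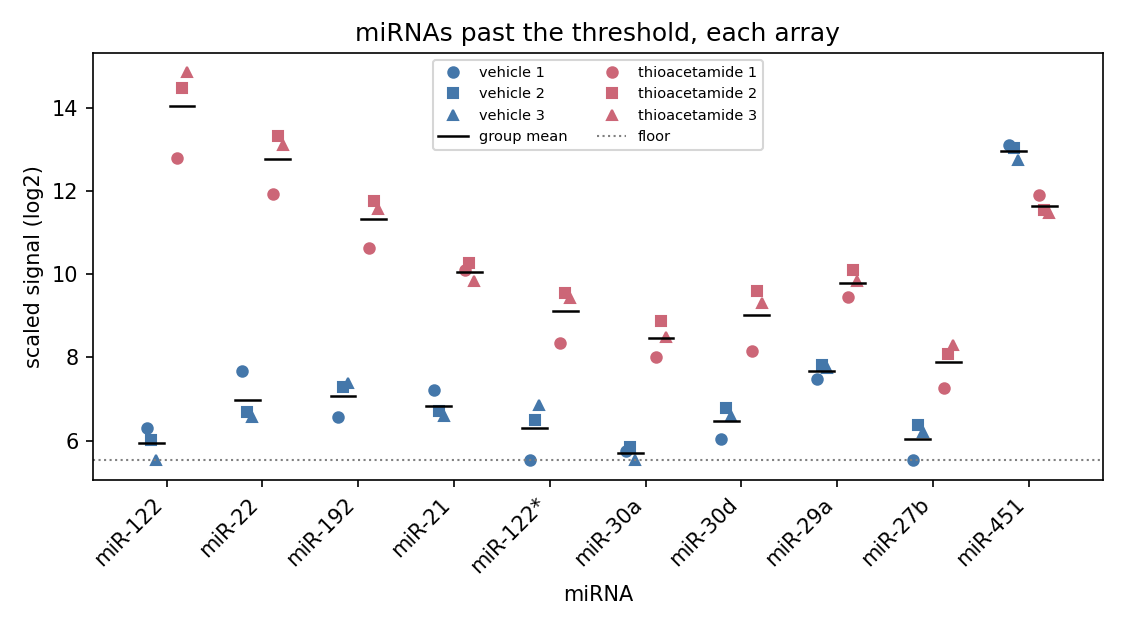
Log2 scaled signal (vertical axis) of the 10 miRNAs past the threshold, with 1 marker per array (blue vehicle, red thioacetamide; marker shape gives the replicate number), black lines at the group means and a dotted line at the floor. The 9 miRNAs that rose have all 3 thioacetamide arrays above all 3 vehicle arrays, and miR-451 has them below; vehicle signals of miR-122* were not well above background, so its means show a measured difference and not the bound.

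With slide side as a block, 12 miRNAs were higher and 2 lower, among them all 10 named so far; miR-193, miR-24, miR-30b-5p and miR-16 were the 4 gained. All 9 risers were higher within both sides, by 0.98 (miR-27b) to 7.03 (miR-122) in columns 1 and 2 and by 2.48 (miR-29a) to 8.37 (miR-122) in columns 3 and 4. As each of the 9 separated the groups, its direction within each side was fixed in advance, and only the sizes inform. Fitted on one side alone, columns 3 and 4 gave 33 higher and 4 lower, and columns 1 and 2 gave 0 by limma, with 11 higher and 5 lower at an unadjusted p under 0.05. Of the calls, 90% were higher; quantile normalization gave 5 higher and 2 lower (71.4%), and scaling to the median of the miRNAs detected on all arrays gave 12 and 4 (75%). The median change of all tested miRNAs was 0.45, and it moved by 0.52 without scaling, 0.64 with spike-in scaling, -0.29 with quantile normalization and -0.42 with that median. Leaving out thioacetamide 1 gave 18 higher and 7 lower, and leaving out vehicle 3 gave 6 and 6. The calls of miR-29a (log2 change 1.37, adjusted p = 0.0744), miR-30d (1.83, adjusted p = 0.0628) and miR-27b (1.31, adjusted p = 0.123) ended without vehicle 3, and that of miR-27b also without vehicle 2 (2.03, adjusted p = 0.0510). Over all alternatives the adjusted p ranged from 0.000173 to 0.370 for miR-30a, 2.77e-05 to 0.302 for miR-122*, 0.000320 to 0.272 for miR-29a, 7.56e-05 to 0.302 for miR-30d and 0.000211 to 0.392 for miR-27b. The calls of miR-30a and miR-122* ended in 6 of 29 and 5 of 26 alternatives, where their log2 changes were as low as 0.93 (a floor 4 times as high) and 1.35 (normexp).

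The liver list was higher as a group than the other tested miRNAs by camera with its preset correlation (adjusted p = 0.00144). It did not pass with an estimated correlation (adjusted p = 0.356). Of its 5 tested members, miR-122, miR-22, miR-192 and miR-122* rose, 0 fell and 1, miR-193, did not pass; adjusted over the list alone, 5 were higher. miR-193, a liver-enriched miRNA, was detected on 0 vehicle and 3 thioacetamide arrays. Its log2 change was 1.59 ± 0.58 (adjusted p = 0.103, or 0.0375 with slide side as a block and 0.000842 to 0.467 over all alternatives). Its bound of 3.1-fold carries no sampling error and does not by itself show a rise. The median log2 change of the list was 4.23, also with miR-122* and miR-193 at their bounds, and it was 3.04 with normexp, 2.20 over members detected on at least 1 array and 1.09 over all 14 members on the array. Leaving out 1 animal gave 3.61 (without vehicle 3) to 5.64 (without thioacetamide 1). Without thioacetamide 1, miR-122* and miR-193 were detected on too few arrays to be tested, so 5.64 is over the remaining members. Fry, which looks at the list by itself, gave an adjusted p = 0.00193. Over all alternatives the adjusted p of the list ranged from 1.98e-11 (camera without a filter, mostly against undetected miRNAs) to 0.356 (estimated correlation). With slide side as a block the median was 4.19 (adjusted p = 0.000426), and it was 3.30 within columns 1 and 2 and 5.08 within columns 3 and 4. miR-122 and miR-122* come from 1 precursor.

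The erythrocyte list was lower than the other tested miRNAs by camera (adjusted p = 0.00490). Its median log2 change was -0.81, against 0.45 for all tested miRNAs. The list's median became 0.01 with spike-in scaling. With an estimated correlation the adjusted p = 0.365, and fry gave an adjusted p = 0.0434. Of its 7 tested members 0 rose, 1 fell and 6 did not pass, and adjusted over the list alone 3 were lower. miR-451, processed by Ago2 and abundant in red blood cells, fell by 1.31 ± 0.34 on the log2 scale (2.49-fold lower, adjusted p = 0.0427), from 12.95 ± 0.20 to 11.64 ± 0.23 (SD, n = 3 per group), and was detected on all 6 arrays. miR-16, another abundant blood cell miRNA, differed by -1.13 ± 0.33 without passing (adjusted p = 0.0585, or 0.0478 with slide side as a block and 0.00343 to 0.841 over all alternatives). It passed without vehicle 3 (-2.02, adjusted p = 0.0297) or thioacetamide 1 (-1.72, adjusted p = 0.0103), and without no other animal. Its change was -0.37 without scaling (adjusted p = 0.762). The other values were -1.35 for miR-106b (adjusted p = 0.0686), -0.81 for miR-15b (adjusted p = 0.137), -0.49 for miR-93 (adjusted p = 0.398), -0.23 for miR-25 (adjusted p = 0.691) and 0.85 for miR-92a (adjusted p = 0.220). Of the 7, 4 are also in the list of the miR-17 cluster with its paralogous clusters and 2 in the plasma reference list.

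miR-451 was lower within columns 1 and 2 (-0.98) and within columns 3 and 4 (-1.60), with an adjusted p = 0.0454 with slide side as a block. It separated the groups, so its direction within each side was fixed in advance. Its change was -0.56 without scaling (adjusted p = 0.598) and -0.49 with spike-in scaling (adjusted p = 0.694), where the call ended; over all alternatives its adjusted p ranged from 0.00206 to 0.694. The call also ended without vehicle 1 (adjusted p = 0.0647), vehicle 2 (0.122), thioacetamide 2 (0.0744) or thioacetamide 3 (0.103), and the change was -2.20 without vehicle 3 and -2.03 without thioacetamide 1. The list's median was -0.88 with slide side as a block (adjusted p = 0.00203), -0.98 within columns 1 and 2 and -0.72 within columns 3 and 4. Leaving out vehicle 1 ended the list's call (adjusted p = 0.120), as did the percentile over all probes (0.0797), no scaling (0.0570), spike-in scaling (0.0590), columns 1 and 2 alone (0.114) and only miRNAs detected on all arrays (0.291); its adjusted p ranged from 0.000431 to 0.365 over all alternatives. Its median was -1.68 without vehicle 3 and -1.28 without thioacetamide 1.

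Of 4 tested leukocyte miRNAs, miR-29a rose, 0 fell and 3 did not pass, also adjusted over the list alone. miR-223, typical of myeloid cells, differed by 0.03 ± 0.54, miR-150, of mature lymphocytes, by -0.91 ± 0.49 and miR-342-3p by -0.48 ± 0.60 on the log2 scale. The list's median was -0.23, its mean 0.19 and its camera adjusted p = 0.865; the median was 0.53 without scaling, 0.60 with spike-in scaling and 0.12 with the percentile over all probes. Leaving out 1 animal moved it from -0.84 (without vehicle 3) to 0.66 (without thioacetamide 3), where fewer than 3 members were tested. Of 10 stellate cell and fibrosis miRNAs, 2 were tested, too few for a list test, and both miR-21 and miR-29a rose, also adjusted over the list alone. The median of these 2 was 2.67, or 1.63 with normexp, and that of all 10 members without a filter was 0. Where a filter left at least 3 members, camera with its preset correlation called the list higher. This held without a filter (adjusted p = 8.03e-06), over miRNAs detected on at least 1 array (0.00275) and with Feature Extraction's detection call (0.00224). Each of these calls includes the risers miR-21 and miR-29a, so they are no separate support for the list. Without a filter 4 of the 10 members were detected on any array, and 578 of the 677 miRNAs compared were detected on none. miR-29a is in both lists.

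Of the platelet and endothelial list 4 miRNAs were tested and 0 passed, also adjusted over the list alone (median 1.06, camera direction lower, adjusted p = 0.967). Its median was 0.19 without vehicle 3, and over all alternatives it ranged from -0.26 (columns 1 and 2) to 1.85 (spike-in scaling). miR-24 differed by 1.91 (adjusted p = 0.0819, or 0.0375 with slide side as a block and 0.00106 to 0.673 over all alternatives), miR-26a by 2.02 (adjusted p = 0.106) and miR-27a by -0.88 (adjusted p = 0.129). Of the plasma reference miRNAs, often used to scale plasma assays, 4 were tested and 0 passed by limma; adjusted over the list alone 2 were higher, miR-24 and miR-26a, and 1, miR-16, lower. That list's median was 0.71 with camera direction lower (adjusted p = 0.865). It was -0.31 in columns 1 and 2, -0.90 (without thioacetamide 3) to 0.72 (without vehicle 2) with 1 animal left out, and -1.13 to 1.50 over all alternatives. Without thioacetamide 3 fewer than 3 members were tested, and the -1.13, over miRNAs detected on all arrays, is the value of miR-16 alone. The 3 tested let-7 miRNAs gave 0 calls, also adjusted over the list alone (median 1.10, camera direction lower, adjusted p = 0.967), with let-7i at -0.83. Without a filter the let-7 list was higher by camera with its preset correlation (adjusted p = 0.00803, median 0.22), set mostly against undetected miRNAs. The list's estimated correlation over the tested miRNAs was 0.77, and camera with it gave an adjusted p = 0.977. The let-7 median was -0.0178 without vehicle 3 and 0 in columns 1 and 2, and over all alternatives the list's adjusted p ranged from 0.00803 to 0.990.

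The miR-17 cluster with its paralogous clusters, transcribed in proliferating cells, had 8 tested members, of which 0 passed by limma, also adjusted over the list alone. Their median was -0.36, which became 0.23 without scaling, 0.30 with spike-in scaling and 0.45 over members detected on all arrays. It was -1.30 without vehicle 3. The camera adjusted p = 0.0827, with 0.789 by an estimated correlation. It passed, in the lower direction, with slide side as a block (0.0245), in columns 3 and 4 alone (0.00547), with the median of miRNAs detected on all arrays (0.0410), over miRNAs detected on at least 1 array (0.0170), without vehicle 2 (0.0428), without vehicle 3 (0.00857) and without thioacetamide 1 (0.0287), with a range of 0.00547 to 0.789 over all alternatives. miR-19b differed by 0.45 ± 0.38. The muscle and heart, brain, pancreas and miR-34 lists had 0 members detected on any array, and the epithelium list with kidney and gut had 5 and the Dlk1-Dio3 cluster 2 detected on some array; these 6 lists had 0 tested members.

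**Figure D2:**
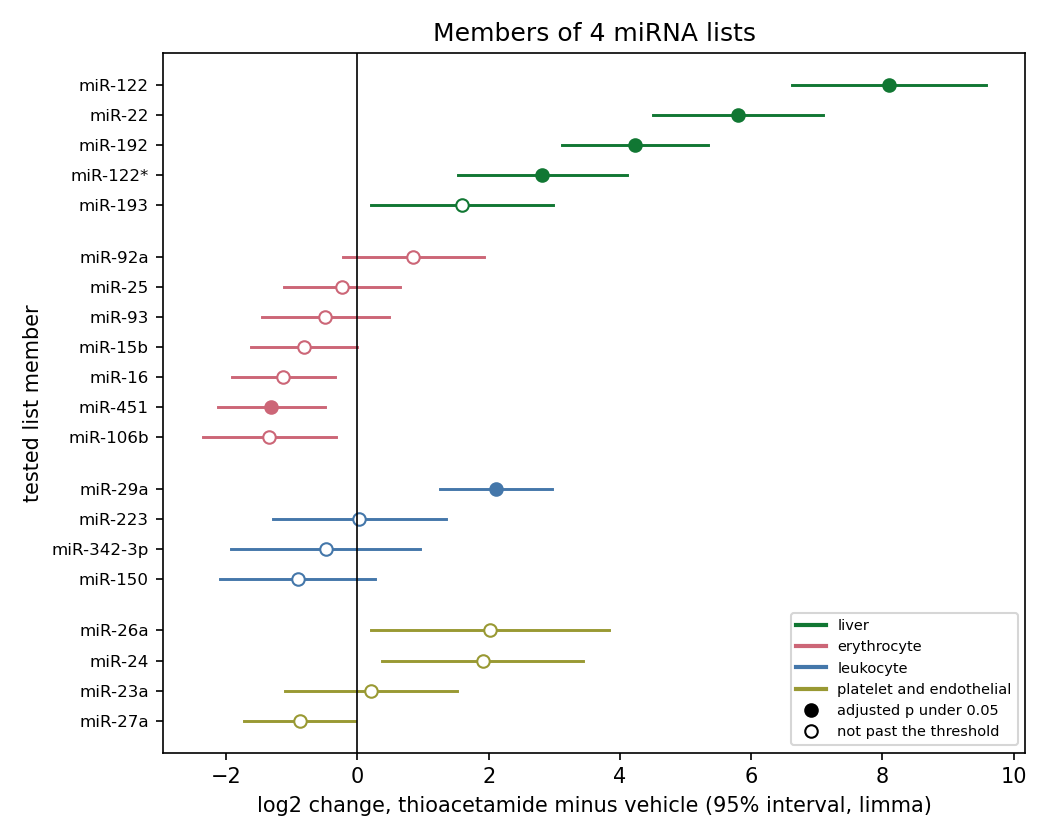
Log2 change (thioacetamide minus vehicle, horizontal axis) with its 95% limma interval for every tested member of the liver, erythrocyte, leukocyte and platelet and endothelial lists; filled markers passed the threshold. All 5 liver members lie above 0, and 6 of 7 erythrocyte members lie below 0, though the erythrocyte median of -0.81 becomes 0.01 with spike-in scaling.

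The miRNAs that made up most of the signal differed between the groups. Shares are of each array's signal before scaling, summed over the 59 tested miRNAs. In vehicle plasma the brightest were miR-451, with 35.4% ± 8.09 (SD, n = 3) of this sum, miR-16 with 12.2% ± 2.98, miR-1224, miR-92a and miR-19b. In treated plasma they were miR-122 with 32.7% ± 8.95, miR-22 with 13.3% ± 1.54, miR-1224 with 7.76% ± 3.51, miR-451 with 6.94% ± 4.75 and miR-192 with 4.84% ± 0.570. The share of miR-122 in vehicle plasma was 0.223% ± 0.181. The shares of miR-122 and miR-451 each separated the groups with an exact permutation p of 0.1, the smallest that 3 against 3 allows. miR-1224 differed by 2.44 ± 0.75 on the log2 scale without passing (adjusted p = 0.0686).

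**Figure D3:**
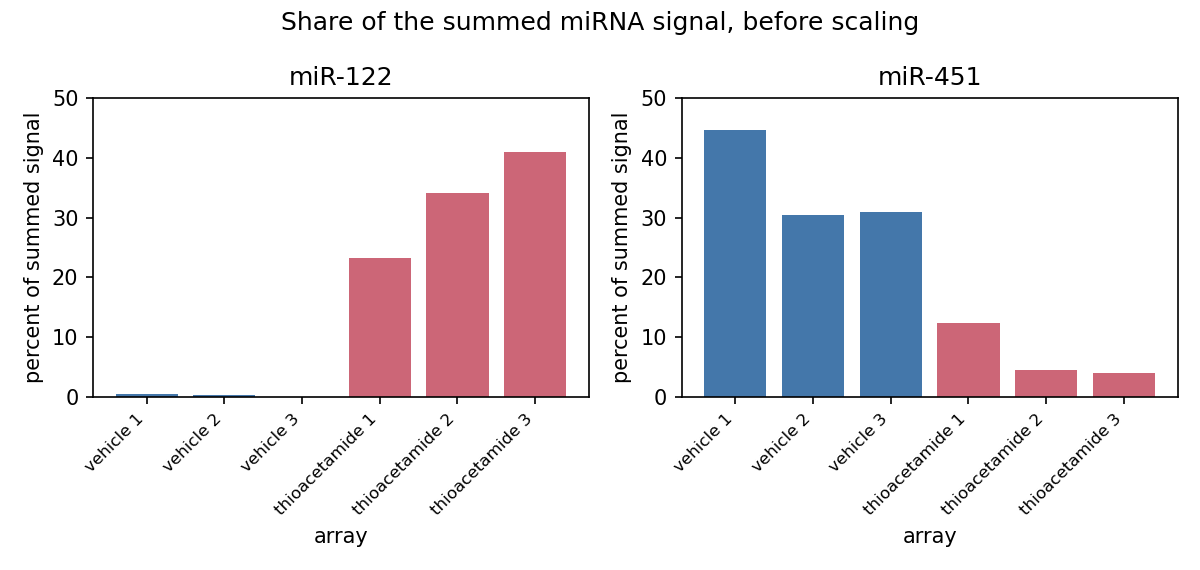
Percent of each array's signal before scaling, summed over the 59 tested miRNAs (vertical axis), held by miR-122 (left) and miR-451 (right), with 1 bar per array (blue vehicle, red thioacetamide). miR-122 held 23.2% to 40.9% on the thioacetamide arrays and at most 0.396% on the vehicle arrays, and miR-451 held 30.5% to 44.7% on the vehicle arrays and at most 12.4% on the thioacetamide arrays.

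The signal summed over the 59 tested miRNAs, from equal plasma volumes, was 3.93-fold higher after thioacetamide (log2 sum 16.07 ± 0.39 against 14.10 ± 0.31, SD, n = 3 per group, exact permutation p = 0.1). Without miR-122 it was 2.63-fold higher (exact permutation p = 0.1). The log2 difference was 2.03 within columns 1 and 2 and 1.89 within columns 3 and 4. Labelling spike-ins differed by -0.07 and hybridisation spike-ins by -0.04 on the log2 scale (exact permutation p = 0.6 and 0.9).

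The number of miRNAs detected per array was 35 ± 24.0 for vehicle (62, 27 and 16) and 58.0 ± 32.0 for thioacetamide (22, 69 and 83), a difference within the spread (exact permutation p = 0.3). It was 0.5 within columns 1 and 2 and 14 within columns 3 and 4. The difference of 23 became 36.5 without vehicle 1, 13.5 without vehicle 3, 41 without thioacetamide 1 and 10.5 without thioacetamide 3.

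All 3 treated rats weighed less at the end than at the start, and all 3 vehicle rats weighed more. The body weight change was -4.52% ± 0.206 after thioacetamide and 0.900% ± 0.142 after vehicle (SD, n = 3 per group), a difference of -5.42 percentage points that separated the groups (exact permutation p = 0.1). In grams the changes were -19.0 ± 1.00 and 3.67 ± 0.577. Start weights were 420.3 g ± 7.51 and 407.7 g ± 16.8 (exact permutation p = 0.3).

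In the rat build rn4 the probes of miR-122 lie on chromosome 18 from 61512764 to 61512782 and those of miR-122* from 61512800 to 61512815. Those of miR-22, miR-21 and miR-451 lie on chromosome 10, from 62782783 to 62782800, from 74864520 to 74864538 and from 64129536 to 64129555. miR-192 maps to chromosome 1 (209040282 to 209040299), miR-30a to chromosome 9 (22142901 to 22142915) and miR-29a to chromosome 4 (58107816 to 58107834). miR-30d maps to chromosome 7 (105819740 to 105819752) and miR-27b to chromosome 17 (7351513 to 7351529). The probes of miR-16 and miR-15b lie close together on chromosome 2, from 158992403 to 158992420 and from 158992256 to 158992274. RefSeq lists a miRNA precursor gene for each of these 12 miRNAs; whether a host transcript overlaps them was not analysed here.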

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

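All tests in this part were chosen after the result was seen. Control probes that enter no miRNA comparison, named hur_1 and hur_2 in the array design, were brighter after thioacetamide than on the vehicle arrays. The 3 hur_1 probes detected on all 6 arrays were brighter by 4.52 on the log2 scale before scaling, from 9.60 ± 1.54 to 14.12 ± 0.36 (SD, n = 3 per group, 23.0-fold, exact permutation p = 0.1, the smallest possible). The 4 such hur_2 probes were brighter by 4.66, from 10.25 ± 1.57 to 14.91 ± 0.58 (25.2-fold, exact permutation p = 0.1). Leaving out 1 animal gave 15.0-fold (without vehicle 1) to 41.7-fold (without vehicle 2) for hur_1 and 18.0-fold (without vehicle 3) to 47.3-fold (without vehicle 2) for hur_2. What these probes bind is not given in the sources used here.

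Stronger labelling on the thioacetamide arrays was tested with the labelling spike-ins, which differed by -0.0662 on the log2 scale. The upper end of their 95% interval, 0.62, lies below 1.15, which is 0.25 of the mean difference of the hur probes, so the spike-ins argue against labelling as the whole cause. The noisier background of slide columns 1 and 2 was tested with slide side as a block, which gave differences of 4.73 (95% interval 1.39 to 8.08) for hur_1 and 4.70 (0.93 to 8.46) for hur_2. Both intervals lie above 0, which argues against a difference between the sides as the whole cause. A biological effect of thioacetamide stays open and was not tested.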

How the results depend on the processing

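The alternatives with slide side, the list tests under settings other than the estimated correlation and fry, and leaving out animals for summed signal and detected miRNAs were chosen after seeing the data. All 9 miRNAs that rose stayed higher in every alternative that tested them (26 or 29 each), and miR-451 stayed lower in all 30, from -2.93 to -0.49. Over these 282 values 227 stayed past the threshold and 55 did not; miR-122, miR-22, miR-192 and miR-21 each lost the threshold in 2 of 29, miR-122* in 5 of 26, miR-29a in 5 of 29, miR-30a in 6 of 29, miR-30d in 7 of 26, miR-27b in 11 of 26 and miR-451 in 13 of 30. Of 529 values for named miRNAs that had not passed, 428 neither passed nor changed sign (miR-30c and miR-93 were 0 with a floor 4 times as high), 75 passed and 26 changed sign. Body weight change, summed signal and the number of miRNAs detected kept their direction in all alternatives run. The deposited matrix, all spots kept and slide row as a block moved no count of calls by over 1.5 times. The cause of the changes given here was not tested, except where fewer or more miRNAs or arrays entered the fit. Signal over background limits the tests, since 8 miRNAs were detected on all 6 arrays.

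Against 9 higher and 1 lower miRNA and 2 lists, the counts were as follows. The percentile over all probes gave 3 higher, 0 lower and 1 list, no scaling 22, 0 and 1, and spike-in scaling 21, 0 and 1. Quantile normalization gave 5 higher and 2 lower, the median of miRNAs detected on all arrays 12 and 4, and normexp 5 and 1. The brightest probe gave 14 and 3, the mean of log2 probes 9 and 2, and the gene signal summed by Feature Extraction 10 and 0. Without a filter (677 tested) there were 2 higher, 0 lower and 4 lists, with detection on all 6 arrays (8 tested) 0, 2 and 0, with detection on at least 1 array (99 tested) 14, 5 and 4, and with Feature Extraction's detection call (87 tested) 9 higher and 0 lower. A floor 0.25 times as high gave 7 and 0, one 4 times as high 7 and 4, a trended robust eBayes 9 and 2, and array weights, whose estimate did not converge, 28 and 13. Slide side as a block gave 12 and 2, columns 3 and 4 alone 33 and 4, and columns 1 and 2 alone 0 and 0 with 1 list. Camera with an estimated correlation called 0 lists. Where limma called 0 lower miRNAs, 0 to 9 were lower at an unadjusted p under 0.05, and where it called 0 higher, 1 (all 6 arrays) and 11 (columns 1 and 2) were higher.

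Leaving out 1 animal at a time gave 6 (without vehicle 3, thioacetamide 2 or thioacetamide 3) to 18 higher (without thioacetamide 1), 0 (without vehicle 1, vehicle 2 or thioacetamide 3) to 7 lower (without thioacetamide 1, and 6 without vehicle 3), and 1 (without vehicle 1) to 3 lists (without vehicle 2, vehicle 3 or thioacetamide 1). The filter left 32 miRNAs to test without vehicle 1, 30 without thioacetamide 2 and 29 without thioacetamide 3. Of the 9 risers 7, 6 and 6 were tested in these settings, in that order, and all of those passed. Only the liver, erythrocyte and miR-17 cluster lists held at least 3 tested members there.

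Several changes that had not passed changed sign, as did the medians of the leukocyte, platelet and endothelial, let-7, miR-17 cluster and plasma reference lists. Some of these medians were over fewer members than in the main fit. miR-25 was 0.0299 with the percentile over all probes, 0.53 without scaling, 0.59 with spike-in scaling and 0.13 in columns 3 and 4. miR-93 was 0.27 without scaling and 0.33 with spike-in scaling, and miR-342-3p 0.27, 0.34 and, in columns 3 and 4, 0.45. With spike-in scaling miR-15b and the erythrocyte median, which it sets, were both 0.0104. miR-92a was -0.30 with quantile normalization and -0.000668 in columns 1 and 2, miR-30c -0.0122 in columns 1 and 2, and miR-30e -0.0199 with normexp. miR-223 was -0.00664 with quantile normalization, -0.34 with the median of miRNAs detected on all arrays, -0.18 with normexp, -0.21 with slide row and -0.25 with slide side as a block, -1.03 in columns 1 and 2, and -0.71 (without vehicle 3) to -0.0179 (without vehicle 2) with an animal left out. miR-19b was -0.23 with quantile normalization and -0.44 (without vehicle 3) to 0.52 with an animal left out, where miR-30e was -0.0576 (without vehicle 3) to 0.71.

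With replicate number as a block (the replicate block), 10 miRNAs were higher and 0 lower, with 3 lower at an unadjusted p under 0.05. The deviations of same-numbered arrays from their group means correlated at -0.70, -0.31 and -0.66, and no array correlated best with its own number. Same-numbered arrays all lay on opposite slide sides. Every vehicle and thioacetamide array on opposite sides correlated negatively, and every such pair on the same side positively. These correlations therefore cannot tell whether the numbers pair the animals, and the main fit did not pair them.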

Other observations

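In this part the counts over other splits of the arrays were planned, and all other tests were chosen after the result was seen. The miR-30 family, which shares a seed sequence, had 5 tested members with log2 changes from 0.57 (miR-30c) to 2.75 (miR-30a). miR-30a and miR-30d passed the threshold, and 4 of the 5, with miR-30b-5p (1.97, adjusted p = 0.0686, or 0.0476 with slide side as a block and 0.000143 to 0.467 over all alternatives) and miR-30e (0.65, adjusted p = 0.220), separated the groups, as did 37.3% of all tested miRNAs. The family was chosen after its values were seen. All 5 were positive under each scaling between arrays, but miR-30e was -0.0199 with normexp and -0.0576 without vehicle 3, and miR-30c was 0 with a floor 4 times as high and -0.0122 in slide columns 1 and 2.

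Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 10 miRNAs past the threshold, and the highest other gave 7. The highest other split parts slide columns 1 and 2 from columns 3 and 4. For lists, 3 of 10 splits gave at least the 2 of the real split, and the highest other gave 3. Such splits are too few for a share under 0.05. Of the 59 tested miRNAs, 9 were brighter and 6 dimmer on all arrays of columns 1 and 2 than on those of columns 3 and 4, with miR-349 (difference 3.52) and miR-3550 (3.22) chosen after their values were seen.

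The 9 miRNAs that rose were weighed against the noisier background on slide columns 1 and 2 and against scaling between the arrays. All 9 passed the threshold with slide side as a block, which argues against a difference between the sides as the whole cause. miR-122, miR-22 and miR-192 passed under each of 5 other scalings, with 1.86 as the lowest lower end of a 95% interval. These 3 were set apart after the results were seen and are the only risers that passed with the percentile over all probes. That they passed is therefore no separate support. None of the 5 scalings brought their log2 changes below 3.46, so the choice among these scalings does not remove their rise. Of the other 6, all passed without scaling, with spike-in scaling and with the median of miRNAs detected on all arrays, 2 passed with quantile normalization (all 6 intervals above 0), and 0 passed under all 5, so scaling stays open for them: with the percentile over all probes their log2 changes were 1.32 to 2.71 (SE 0.73 to 0.94), against 1.84 to 3.22 (SE 0.35 to 0.53), and their calls ended with this wider spread and mostly smaller changes. A biological effect of thioacetamide stays open and was not tested.

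The lower miR-451 and miR-16 were weighed against scaling between the arrays and against less erythrocyte RNA in the plasma. Without scaling miR-451 differed by -0.56, with a 95% interval from -1.95 to 0.84 that holds both 0 and the scaled change of -1.31, so scaling stays open. Less erythrocyte RNA was predicted to lower every member of the erythrocyte list, which assumes that these miRNAs have no other source in plasma. Of 7 tested members, 4 had a 95% interval below 0 and 0 had one above 0. These scaled values cannot decide, since members of the list also set the scale. Without scaling the list's median was -0.06, with changes from -0.59 (miR-106b) to 1.61 (miR-92a). Less erythrocyte RNA therefore stays open too. miR-451 and miR-16 stood at scaled log2 signals of 12.95 and 11.41 in vehicle plasma and 11.64 and 10.28 after thioacetamide. The share of miR-451 in the summed signal was 35.4% in vehicle plasma and 6.94% after thioacetamide, while the sum itself was 3.93-fold higher. A lower share was thus measured. A lower amount was not shown and is not excluded, since the interval without scaling holds 0. A biological effect of thioacetamide was not tested.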
